A study of Homo sapiens with 3 samples.

How the data were processed

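RNA sequencing libraries from Caco-2 cells, a human colon carcinoma line used as a model of the intestinal epithelium, were compared across 3 groups with 1 library each. The groups were untreated control cells, cells given 3% dextran sulfate sodium (DSS) for 8 h, and cells given 30 µM polydatin for 2 h before and then together with DSS. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a VAHTS Universal RNA-seq kit. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCh38. The aligner's version, the counting program, the annotation release and the strand setting are not given in the sources used here. The deposited table holds raw read counts per Ensembl gene, as whole numbers with no normalization, for 60664 gene identifiers. Groups of cells given erastin or a ferroptosis inhibitor that the design text mentions were not analysed here.

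Library totals were 18695613 counts for control, 18825914 for DSS and 16667622 for DSS with polydatin. Gene symbols were matched for 60463 identifiers (99.7%). Coordinates, gene types, GC content and transcript length came from GENCODE release 29 on GRCh38, which holds 58396 of the identifiers. The strand setting being unknown, reads of overlapping or antisense genes cannot be separated, and reads of near-identical copies could be split or dropped by the counting.

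Counts were scaled with trimmed-mean-of-M (TMM) factors from edgeR 4.0.16 in R 4.3.3. The factors were 0.971 for control, 0.984 for DSS and 1.05 for DSS with polydatin. A gene was measured when its CPM (the count relative to the scaled library total) reached 1 in at least 1 library, which held for 14792 genes, of which 12279 are protein-coding. For each gene and each of 3 comparisons the ratio of scaled counts was computed with an exact 95% Clopper-Pearson interval on the counts of both libraries, in Python 3.11.15 with scipy 1.17.1. In ratios where either library had a count of 0, 0.5 was added to the counts of both libraries. A CPM of 1 corresponded to 18.2 counts in control, 18.5 in DSS and 17.4 in DSS with polydatin, and 3 counts to 0.165, 0.162 and 0.172 CPM. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. With 1 library per group there are no replicates, and no p-value, standard error or test of the conditions is given. Each ratio compares libraries, not conditions.

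The number of genes at least 2-fold apart with an interval excluding 1 was counted in each comparison. A total of 31 gene lists was fixed before the data were examined. For each list the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called apart at a percentile of at most 2.5 or at least 97.5. List members were counted as higher or lower at 1.5-fold with an interval excluding 1. Some genes stand in several lists, among them SLC7A11, CHAC1 and MYC. The genes named were set by rule. They are NFE2L2, KEAP1, SLC7A11 and GPX4, then the 8 highest and 8 lowest genes of each main comparison ranked by the interval bound nearest to 1 at a CPM of at least 5 (4 each way for DSS with polydatin against control), then up to 4 members of each list apart and of the ferroptosis, iron and NRF2 lists. Other named genes are said to be chosen after their values were seen.

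The DSS library enters both main comparisons, so 3 libraries with no difference were simulated 20 times each with Poisson counts and with coefficients of variation of 0.1 and 0.2. The ratios and list percentiles were tested on Poisson counts, simulated for each gene independently, for DSS against control with 200 changed genes among 14561 measured. All genes changed 4-fold either way were recovered (100%). Of those simulated at 2-fold, on the threshold, 56% of higher and 48% of lower genes were recovered. The interval covered the true value in 95.2% of 14361 unchanged genes, of which 60 were called at 2-fold. It covered it in 94% of genes simulated 4-fold higher, 92% at 2-fold higher, 94% at 2-fold lower and 88% at 4-fold lower. Of random lists of unchanged genes, 12 of 200 were called apart (6%). These simulated counts leave out genes that move together and spread between cultures. The 6% is therefore not the rate of false calls for the gene lists used here.

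Alternatives to the main settings were total-count scaling, DESeq2 1.42.0 size factors, no filter, a CPM of at least 10, thinning to the smallest library, a 1.5-fold rule, 2 counts added to each library, and the mean of list members in place of the median. Removal of a smooth trend on GC content and transcript length (statsmodels 0.14.6) was added after the data were examined. Figures were drawn with matplotlib 3.10.9.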

Results

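The data are gene-level RNA read counts from 3 libraries of Caco-2 cells, 1 for each of control, DSS and DSS with polydatin. DSS is a sulfated polysaccharide widely used to provoke colitis in rodents, and polydatin is a glucoside of resveratrol. Judging by the title of the series, the study asked whether polydatin acts on DSS-induced injury through NRF2 (encoded by NFE2L2), SLC7A11 and GPX4, genes tied to ferroptosis, an iron-dependent form of cell death with lipid peroxidation. Library totals were 18695613 counts for control, 18825914 for DSS and 16667622 for DSS with polydatin. Genes with at least 1 count numbered 24286, 24811 and 25251, and with libraries thinned to the same total count 23909, 24384 and 25251. The 10 most abundant genes held 6.19%, 6.14% and 5.67% of counts. Mitochondrially encoded transcripts held 5.31% of control counts (95% exact interval 5.30 to 5.32), 4.77% of DSS counts (4.76 to 4.78) and 4.34% of DSS with polydatin counts (4.33 to 4.35). There are no replicates, so every difference given here lacks a replicate check. Except for Wilson intervals of shares of genes, the intervals in parentheses are 95% counting intervals that cover counting error only.

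DSS against control asks what DSS did to these cells. SLC7A11 (chromosome 4, 138164097 to 138242349, GRCh38), which encodes the cystine importer that feeds glutathione synthesis, had 4128 counts in control and 1548 in DSS, 0.368 times the control level (0.346 to 0.390). GPX4 (chromosome 19, 1103926 to 1106791), the peroxidase that reduces lipid peroxides, was at 0.889 times control (0.837 to 0.944). NFE2L2 (chromosome 2, 177227595 to 177392697) was at 1.31 times control (1.25 to 1.38), and KEAP1 (chromosome 19, 10486120 to 10503741), which encodes the protein that targets NRF2 for degradation, at 1.27 times (1.17 to 1.38). Over all measured genes, 627 were at least 2-fold higher and 261 at least 2-fold lower in DSS than in control, of which 478 and 169 are protein-coding. Simulated libraries with no difference gave 51.4 such genes in all with Poisson counts, 85.0 at a coefficient of variation of 0.1 and 479 at 0.2, against the 888 observed. Removing the GC content and length trend brought the KEAP1 log2 ratio from 0.34 to 0.14 and the GPX4 log2 ratio from −0.17 to −0.35.

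**Figure D1:**
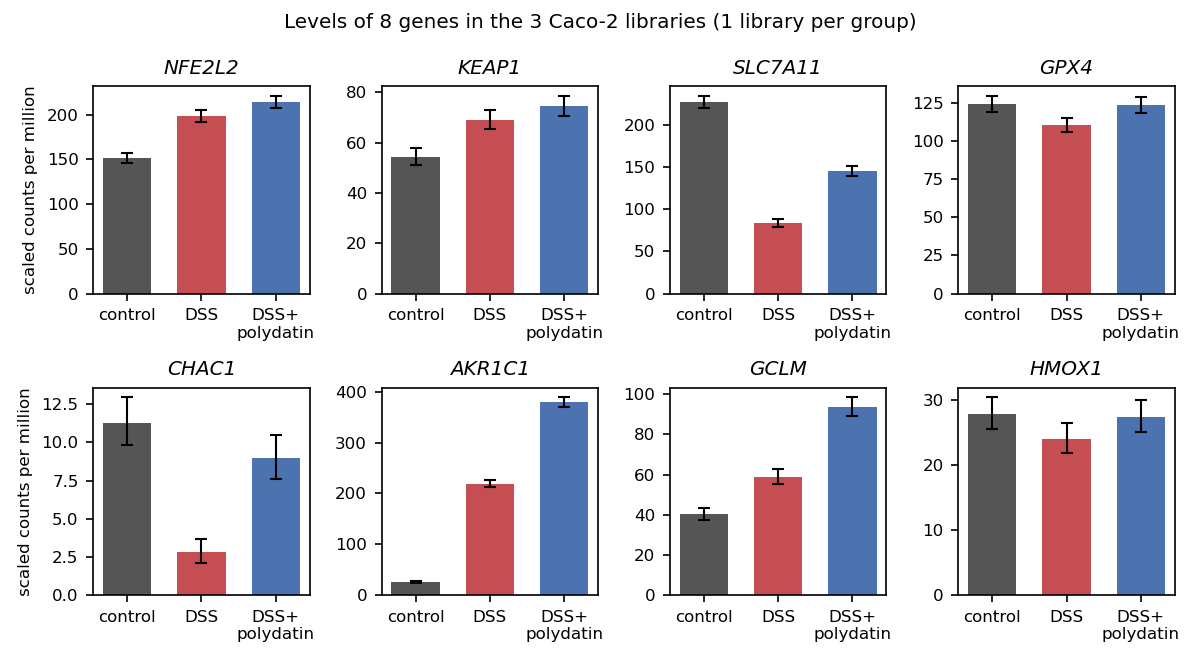
Scaled CPM (vertical axes, each starting at 0) of 8 genes in the control, DSS and DSS with polydatin libraries, 1 library per bar, with 95% Poisson counting intervals as error bars. SLC7A11 and CHAC1 were lowest in DSS, while AKR1C1 and GCLM were higher in DSS than in control and higher again in DSS with polydatin. By smaller margins GPX4 (124, 111 and 124 CPM) and HMOX1 (27.9, 24.1 and 27.4 CPM) were also lowest in DSS. The HMOX1 intervals overlap. HMOX1 was plotted outside the naming rule.

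NRF2 target genes were higher as a list in DSS, with a median log2 ratio of 0.42 over 30 measured members (percentile 100 among random lists). Of these, 9 were at least 1.5-fold higher and 1, SLC7A11, was lower by as much, with 24 above 0 and 6 below. The aldo-keto reductase genes AKR1C1 and AKR1C2 were 8.39-fold (7.63 to 9.25) and 5.73-fold (5.30 to 6.19) higher, and OSGIN1 was 3.11-fold higher (2.31 to 4.24). AKR1C1 and AKR1C2 are near-identical in sequence, so the split of reads between them is uncertain. The list of ferroptosis and glutathione defence genes had a median of −0.03 over 19 members (percentile 45.7), with 2 higher and 2 lower. SCD, a fatty acid desaturase, was 1.86-fold higher (1.84 to 1.88) and AIFM2, which encodes ferroptosis suppressor protein, 1.56-fold higher (1.38 to 1.75), while CBS was at 0.464 times control (0.346 to 0.618). The ferroptosis-promoting list had a median of 0.22 over 18 members (percentile 99.6), with 1 higher, DPP4 at 1.64-fold (1.57 to 1.70), and 1 lower, CHAC1, which degrades glutathione, at 0.249 times control (0.180 to 0.339). FADS2 was at 1.5 times control (1.33 to 1.70) and LPCAT3 at 1.31 times (1.22 to 1.41). The iron list had a median of 0.21 over 20 members (percentile 99.6), with none lower and 1, CYBRD1, higher at 1.79-fold (1.05 to 3.12), a gene named here after its value was seen. The ferritin genes FTH1 and FTL were at 1.42 times (1.39 to 1.46) and 1.21 times (1.19 to 1.23) control, the iron exporter gene SLC40A1 at 0.786 times (0.757 to 0.816) and HEPH at 1.23 times (1.17 to 1.29). With the mean in place of the median, the ferroptosis-promoting list (mean 0.07, percentile 71.5) and the iron list (mean 0.17, percentile 92.9) were no longer apart.

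Genes of the ATF4 and integrated stress response list were lower in DSS, with a median log2 ratio of −0.73 over 25 members (percentile 0). Of these, 16 were lower and 2 higher. The serine synthesis genes PSAT1 and PHGDH were at 0.287 times (0.269 to 0.306) and 0.364 times (0.348 to 0.381) control. Among the lowest genes overall were also INHBE at 0.106 times control (0.0566 to 0.185), the mitochondrial folate enzyme gene ALDH1L2 at 0.266 times (0.211 to 0.333) and GPX8 at 0.232 times (0.177 to 0.30). The sucrase-isomaltase gene SI was at 0.198 times control (0.167 to 0.233), the fibrinogen gene FGG at 0.251 times (0.209 to 0.299) and the ephrin receptor gene EPHA4 at 0.295 times (0.260 to 0.335).

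Cholesterol synthesis genes were higher in DSS, with a median log2 ratio of 0.76 over 25 members (percentile 100). Of these, 17 were higher and none lower, among them LSS at 2.65-fold (2.52 to 2.79), MVD at 2.44-fold (2.23 to 2.67) and TM7SF2 at 2.43-fold (2.12 to 2.78). Immediate early genes had a median of 0.90 over 21 members, with 12 higher and 1 lower, and NF-κB and inflammatory mediators a median of 0.71 over 20 members, with 9 higher and 1 lower (both at percentile 100). The MAP kinase phosphatase genes DUSP5 and DUSP4 were 6.31-fold (5.27 to 7.61) and 5.55-fold (3.91 to 8.05) higher, KLF6 was 3.84-fold higher (3.53 to 4.17), the chemokine gene CCL2 was 2.82-fold higher (2.16 to 3.72) and the adhesion molecule gene ICAM1 2.36-fold higher (2.05 to 2.73). Hypoxia and glycolysis genes had a median of 0.61 over 24 members (percentile 100), with 13 higher and 1 lower, and PFKFB4 was 3.12-fold higher (2.57 to 3.80). Tight and adherens junction genes had a median of 0.25 over 23 members (percentile 99.9), with 6 higher and none lower. The claudin genes CLDN3 and CLDN4 were 4.10-fold (2.86 to 6.01) and 2.53-fold (2.38 to 2.69) higher. The TGF-β and epithelial-mesenchymal transition list had a median of 0.35 over 17 members (percentile 99.7), with 6 higher and 1 lower and FN1, fibronectin, 2.29-fold higher (2.22 to 2.36). The p53 target list had a median of 0.24 over 19 members (percentile 99.2), with 5 higher and 1 lower. GDF15 was 6.30-fold higher (5.33 to 7.47) and the cell cycle inhibitor gene CDKN1A 4.73-fold higher (3.61 to 6.30). That list was not apart under 4 alternatives, at percentile 92.3 with a CPM of at least 10.

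Proliferation genes were lower in DSS. The mitosis list had a median log2 ratio of −0.61 over 20 members, with 10 lower and none higher, and the DNA replication list a median of −0.49 over 23 members, with 6 lower and none higher (both at percentile 0). CENPE was at 0.492 times control (0.462 to 0.523), CENPF at 0.543 times (0.524 to 0.562) and RFC4 at 0.519 times (0.489 to 0.550). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails and whose list was fixed as a check of poly(A) selection between libraries, were higher, with a median of 0.85 over 14 members (percentile 100) and 9 of them higher. H2BC5 was 3.18-fold higher (2.66 to 3.83) and H2AC6 2.85-fold (2.47 to 3.30). A difference in poly(A) selection between the control library and the DSS library therefore stays open and was not tested further. Mitochondrially encoded transcripts had a median of −0.21 over 13 members (percentile 2.05), which with the GC content and length trend removed was −0.09 (percentile 21.3), and the list was not apart under 4 alternatives.

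The highest genes in DSS were led by SLC6A12 (chromosome 12, 190077 to 214570), a betaine and GABA transporter gene, with 15 counts in control and 1016 in DSS, 66.4-fold higher (40.1 to 119). SLC6A12 overlaps 2 other genes in the annotation, and with the strand setting unknown reads of these cannot be separated. CAPN8, a calpain gene, was 28.6-fold higher (23.2 to 35.6), the long noncoding RNA UCA1 10.6-fold (9.74 to 11.6) and CLTRN, collectrin, 14.6-fold (8.53 to 27.2). The cadherin gene CDH16 was 32.6-fold higher, from 4 counts in control (12.4 to 121). The alkaline phosphatase genes ALPP and ALPG were 15.7-fold (12.6 to 19.7) and 10.3-fold (8.43 to 12.7) higher, with reads shared between these near-identical copies left uncertain. In all, 15 of the 31 lists were apart. Lists not apart were ER chaperones (median 0.08), heat shock (0.00), interferon-stimulated (0.26), mucins and goblet cell markers (0.31), enterocyte differentiation (0.09), metallothioneins (−0.07), apoptosis (0.02), WNT targets (0.16), ribosomal proteins (−0.09) and housekeeping genes (0.04). The aryl hydrocarbon receptor list (0.19) was also not apart, and its mean had the opposite sign (−0.09), as did that of the heat shock list (0.06). Under alternatives some of these came to stand apart. The mucin list had a median of 1.56 without the filter on low counts and a mean of 1.29 (both at percentile 100), and the aryl hydrocarbon receptor list a median of 0.43 with a CPM of at least 10 (percentile 99.9) and 0.24 without the filter (percentile 98.9). By their means the interferon-stimulated list (0.47, percentile 99.2) and the WNT list (0.30, percentile 97.8) stood apart. So did ER chaperones with the GC content and length trend removed (0.14, percentile 99.5) and metallothioneins without the filter (−0.62, percentile 0.69).

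**Figure D2:**
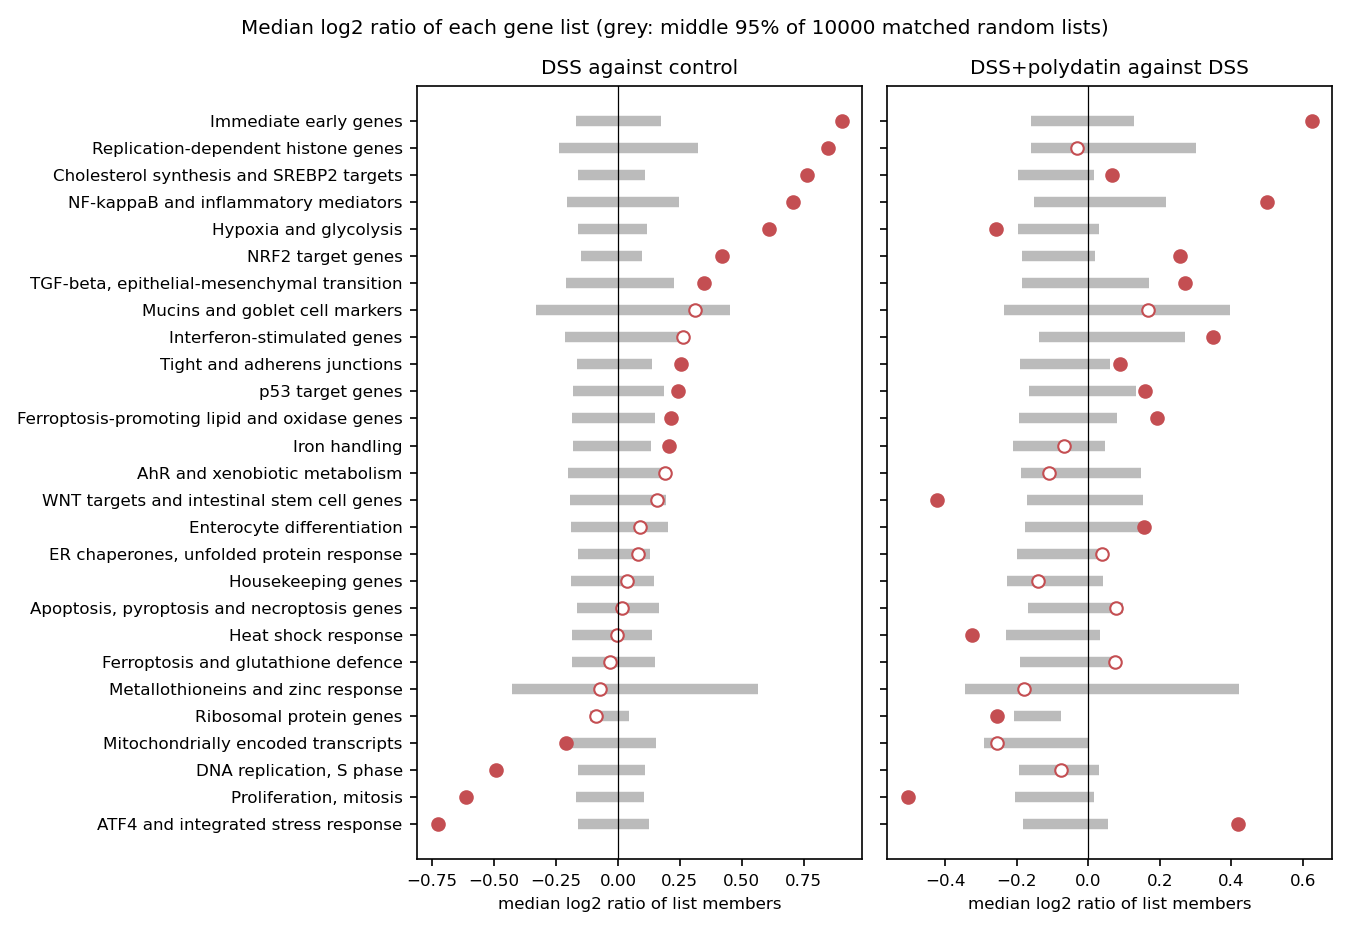
Median log2 ratio (horizontal axis) of 27 gene lists (vertical axis) for DSS against control and DSS with polydatin against DSS, 1 library per group. Filled points are lists apart from 10000 matched random lists, open points are not, and grey bars span the middle 95% of random medians. ATF4 genes lay at −0.73 and then 0.42, and mitosis genes at −0.61 and −0.51.

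DSS with polydatin against DSS asks how cells given polydatin with DSS differed from cells given DSS alone. SLC7A11 had 1548 counts in DSS and 2534 with polydatin, 1.74-fold higher (1.63 to 1.85). GPX4 was at 1.12 times the DSS level (1.05 to 1.19) and NFE2L2 at 1.08 times (1.03 to 1.13), while the KEAP1 ratio of 1.08 had an interval that reached 1 (0.997 to 1.16). Fewer genes were apart than in the DSS comparison, with 287 at least 2-fold higher and 68 at least 2-fold lower, of which 175 and 30 are protein-coding. With a CPM of at least 10 the counts were 30 and 9, so most of the genes called lay below that CPM. The 355 genes in all compare with 51.0 in simulated libraries with no difference and Poisson counts, 86.9 at a coefficient of variation of 0.1 and 479.9 at 0.2, so the number does not exceed what the widest simulated spread gives. Total-count scaling moved the GPX4 log2 ratio from 0.16 to 0.25 and the NFE2L2 log2 ratio from 0.11 to 0.20, and removal of the GC content and length trend took the KEAP1 log2 ratio from 0.11 to −0.040.

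NRF2 target genes were higher again with polydatin, with a median log2 ratio of 0.26 over 30 members (percentile 100). Of these, 8 were at least 1.5-fold higher and none lower by as much, with 22 above 0 and 8 below. NQO1, named after its value was seen, was among those below, at 668 CPM in DSS and 606 with polydatin. OSGIN1 was 2.27-fold higher (1.90 to 2.71), the transporter gene ABCC3 1.79-fold (1.69 to 1.90) and AKR1C1 1.73-fold (1.67 to 1.80). ATF4 list genes, lower in DSS, were higher with polydatin, with a median of 0.42 over 25 members (percentile 100) and 8 higher and none lower. CHAC1 was 3.19-fold higher (2.32 to 4.45), the lipoprotein receptor gene VLDLR 2.48-fold (1.99 to 3.10) and the transcription factor gene ATF3 2.07-fold (1.87 to 2.30). Unlike the list, ATF3 was already higher in DSS (30.7 CPM) than in control (14.4 CPM). ALDH1L2 was 2.95-fold higher (2.33 to 3.75). The ferroptosis and glutathione defence list had a median of 0.08 over 19 members (percentile 96.8), short of apart, and a mean of 0.08 that was apart (percentile 97.8), with 3 higher and 1 lower. The thioredoxin reductase gene TXNRD1 was 1.61-fold higher (1.57 to 1.66) and the glutathione synthesis gene GCLM 1.59-fold (1.47 to 1.72), while DHODH was at 0.552 times DSS (0.426 to 0.711). The ferroptosis-promoting list had a median of 0.19 over 18 members (percentile 99.96), with 4 higher and 1 lower. In it SAT1 was 1.61-fold higher (1.52 to 1.69), ACSL1 1.68-fold higher (1.38 to 2.04) and the NADPH oxidase gene NOX1 at 0.549 times DSS (0.497 to 0.607). The iron list was not apart (median −0.07, percentile 62.0), with no member past 1.5-fold. The transferrin receptor gene TFRC was at 0.727 times DSS (0.713 to 0.740), SLC11A2 at 0.756 times (0.711 to 0.803), CISD1 at 0.795 times (0.729 to 0.867) and SLC40A1 at 1.30 times (1.25 to 1.35).

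Some lists that were apart and higher in DSS were apart and higher again with polydatin. Immediate early genes had a median log2 ratio of 0.62 over 21 members (12 higher, 2 lower) and NF-κB and inflammatory mediators a median of 0.50 over 20 members (7 higher, none lower), both at percentile 100. DUSP5 was 2.12-fold higher (1.96 to 2.30), the apoptosis inhibitor gene BIRC3 2.00-fold (1.79 to 2.23), IL18 1.91-fold (1.66 to 2.21) and NFKB2 1.74-fold (1.55 to 1.94). Unlike its list, IL18 was lower in DSS (16.4 CPM) than in control (25.2 CPM). Interferon-stimulated genes, not apart for DSS against control by their median, had a median of 0.35 over 20 members (percentile 99.6), with 2 higher, IRF7 at 2.82-fold (2.01 to 4.00) and GBP2 at 1.54-fold (1.35 to 1.75). The p53 target list had a median of 0.16 over 19 members (percentile 98.8), with 4 higher, and CDKN1A was 2.37-fold (2.07 to 2.72) and GDF15 1.97-fold (1.82 to 2.12) higher. It was not apart with a CPM of at least 10 (percentile 92.6). The TGF-β and epithelial-mesenchymal transition list had a median of 0.27 over 17 members (percentile 99.9), with 2 higher and 1 lower. GREM1, which encodes a BMP antagonist and is in none of these lists, was 2.53-fold higher (1.97 to 3.27). It had been lower in DSS (4.91 CPM) than in control (7.21 CPM).

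Hypoxia and glycolysis genes, higher in DSS, were lower with polydatin, with a median log2 ratio of −0.26 over 24 members (percentile 0.180) and 3 lower and none higher. The glucose transporter gene SLC2A1 was at 0.536 times DSS (0.524 to 0.548) and LDHA at 0.620 times (0.607 to 0.632). Mitosis genes were lower again, with a median of −0.51 over 20 members (percentile 0) and 5 lower. CDC20 was at 0.50 times DSS (0.457 to 0.546), PLK1 at 0.507 times (0.461 to 0.557) and PTTG1, securin, at 0.484 times (0.451 to 0.520). WNT targets and stem cell genes had a median of −0.42 over 18 members (percentile 0), with 5 lower and none higher. MYC was at 0.555 times DSS (0.527 to 0.586) and AXIN2, a feedback inhibitor of WNT signalling, at 0.610 times (0.536 to 0.694). Heat shock genes had a median of −0.33 over 17 members (percentile 0.0800), with 4 lower, among them HSPD1 at 0.636 times DSS (0.624 to 0.647). Ribosomal protein genes had a median of −0.26 over 52 members (percentile 0.0600), with none past 1.5-fold. CLDN2, a pore-forming claudin gene, was at 0.403 times DSS (0.367 to 0.443), CYP1A1, a target of the aryl hydrocarbon receptor, at 0.419 times (0.383 to 0.458), ID1 at 0.436 times (0.379 to 0.50) and MGAM2 at 0.406 times (0.294 to 0.555).

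Cholesterol genes differed little with polydatin, with a median of 0.07 over 25 members (percentile 99.7) and none past 1.5-fold. The junction list had a median of 0.09 over 23 members (percentile 99.1), with CLDN3 1.56-fold higher (1.27 to 1.92) and CLDN2 lower, and was not apart by its mean (percentile 96.2). The enterocyte list had a median of 0.16 over 20 members (percentile 98.2), with 13 above 0, 2 past 1.5-fold higher and 2 lower. It was not apart under 4 alternatives, with a median of 0.06 without the filter (percentile 71.5), −0.051 with a CPM of at least 10 (percentile 58.7) and 0.10 with the GC content and length trend removed (percentile 97.0), and a mean of 0.16 (percentile 94.2). The 4 members named by rule, which requires a CPM of at least 5, were lower, APOB at 0.634 times DSS (0.588 to 0.684), CDX2 at 0.665 times (0.621 to 0.712), HNF4A at 0.686 times (0.662 to 0.710) and FABP1 at 0.689 times (0.654 to 0.726). Lists not apart were DNA replication (median −0.08), histones (−0.03), mitochondrially encoded (−0.25), mucins and goblet cell markers (0.17), ER chaperones (0.04), aryl hydrocarbon receptor (−0.11), metallothioneins (−0.18), apoptosis (0.08) and housekeeping genes (−0.14). By their means the apoptosis list (0.14, percentile 99.4) and ER chaperones (0.05, percentile 98.4) stood apart, the latter also with a CPM of at least 10 (percentile 98.8). The highest ratio by rank was that of BOLA2B, with 3, 4 and 114 counts in control, DSS and DSS with polydatin (30.3-fold, 11.5 to 113). Its near-identical copy BOLA2 had a count of 0 in the 3 libraries, so the BOLA2B value is uncertain. In all, 17 of the 31 lists were apart.

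DSS with polydatin against control shows where the treated cells stood relative to untreated cells. SLC7A11 was at 0.639 times control (0.608 to 0.672) and GPX4 at 0.993 times (0.936 to 1.05), with the sign of the GPX4 log2 ratio turning from −0.01 to 0.10 under total-count scaling. NFE2L2 was at 1.41 times control (1.35 to 1.49) and KEAP1 at 1.37 times (1.26 to 1.49). A total of 1262 genes was at least 2-fold higher and 483 at least 2-fold lower, 72.3% higher, and under total-count scaling 1586 and 337, 82.5% higher. The 1745 genes in all compare with 481 in simulated libraries with no difference at a coefficient of variation of 0.2. That scaling placed the median log2 ratio of all genes at 0.09, against −0.02 with TMM factors.

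NRF2 target genes stood at a median log2 ratio of 0.63 (percentile 100), with 14 of 30 higher and 2 lower. AKR1C1 was 14.6-fold higher (13.3 to 16), OSGIN1 7.04-fold (5.35 to 9.42) and the autophagy receptor gene SQSTM1 4.33-fold (4.15 to 4.5). The ferroptosis and glutathione defence list was not apart (median −0.07, mean 0.01, percentile 55.1), with 5 higher and 4 lower. GCLM was 2.32-fold (2.12 to 2.53) and TXNRD1 2.31-fold (2.24 to 2.39) higher, and DHODH was at 0.426 times control (0.332 to 0.544). The ferroptosis-promoting list had a median of 0.40 (percentile 99.9), with 5 higher and 2 lower, and SAT1 was 2.07-fold (1.95 to 2.19) and PTGS2, cyclooxygenase-2, 1.70-fold (1.54 to 1.88) higher. The iron list was not apart (median 0.00, percentile 82.9), with FTH1 1.66-fold higher (1.62 to 1.70). ATF4 list genes were lower than in control, with a median of −0.34 (percentile 1.83, and no longer apart with a CPM of at least 10, at 4.12, or thinned, at 2.68) and 10 of 25 lower and 3 higher. PSAT1 was at 0.346 times control (0.326 to 0.368), while ATF3 was 4.41-fold higher (3.85 to 5.07).

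Medians relative to control were also high for immediate early genes (1.14, 14 of 21 higher), NF-κB mediators (1.11, 12 of 20), interferon-stimulated genes (0.79, 11 of 20) and cholesterol synthesis (0.77, 15 of 25). The same held for the TGF-β list (0.76, 10 of 17 higher), histones (0.67, 7 of 14), junctions (0.33, 7 of 23), hypoxia and glycolysis (0.23, 8 of 24) and mucins and goblet cell markers (0.81, 6 of 11). GBP2 was 12.6-fold (9.38 to 17.2), KLF6 6.05-fold (5.6 to 6.56) and MUC3A 1.95-fold (1.64 to 2.33) higher. Medians were low for mitosis (−1.22, 19 of 20 lower), DNA replication (−0.60, 12 of 23), ribosomal proteins (−0.34, 3 of 52) and WNT targets (−0.30, 3 of 18). KIF20A was at 0.311 times control (0.291 to 0.332) and MCM6 at 0.424 times (0.406 to 0.442). The WNT list was not apart under 4 alternatives, at percentile 21.6 by its mean. The highest genes were SLC6A12 (88.2-fold, 53.3 to 158), CAPN8 (41.3-fold, 33.5 to 51.4), CDH16 (48.2-fold, 18.5 to 179) and UCA1 (16.5-fold, 15.2 to 18.1). The lowest were ID1 at 0.171 times control (0.151 to 0.194), SI at 0.182 times (0.152 to 0.217), FGG at 0.203 times (0.165 to 0.247) and GNG2 at 0.168 times (0.101 to 0.268). Lists not apart were p53 targets (median 0.25), enterocyte (0.16), ER chaperones (0.10), heat shock (−0.17), aryl hydrocarbon receptor (0.06, mean −0.18), metallothioneins (−0.26), apoptosis (0.05), mitochondrially encoded (−0.36) and housekeeping genes (−0.11). Under alternatives, p53 targets stood apart by their mean (0.61, percentile 99.99), without the filter (0.31, percentile 98.5) and with the GC content and length trend removed (0.22, percentile 99.1). The aryl hydrocarbon receptor list did so with a CPM of at least 10 (0.46, percentile 99.9), metallothioneins without the filter (−1.12, percentile 0.01), and mitochondrially encoded transcripts by their mean (−0.40, percentile 1.71). ER chaperones did so with a CPM of at least 10 (0.13, percentile 98.1) and with the trend removed (0.18, percentile 99.8). The histone list was not apart without the filter (0.53, percentile 93.5).

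Of the 888 genes at least 2-fold apart between DSS and control, 340 lay closer to control with polydatin, 38.3% (95% Wilson interval 35.1 to 41.5). The Wilson intervals of these shares take genes as independent, which they are not, and leave out the spread between cultures. The DSS library is shared by both comparisons, and 3 simulated libraries with no difference gave 91.0% with Poisson counts. This simulated share was not split into genes higher and lower in DSS. Of the 261 genes lower in DSS, 182 lay closer to control with polydatin (69.7%, 63.9 to 75), and 46 were back by at least 1.5-fold while 9 were further away. Of the 627 genes higher in DSS, 158 lay closer (25.2%, 22.0 to 28.7), 15 were back by at least 1.5-fold and 138 were further away. Across 14792 genes, which are not independent replicates, the log2 ratios of both comparisons correlated at Pearson r = 0.15 and Spearman rho = 0.23. Their covariance was 0.0358, against −0.0234 in simulated Poisson libraries, −0.0445 at a coefficient of variation of 0.1 and −0.111 at 0.2. Genes higher by 1.5-fold in DSS and higher again with polydatin numbered 212, where independent lists would share 75.3. Genes lower in DSS and higher with polydatin numbered 74, where independent lists would share 46.3. Genes lower in both numbered 45, against 22.3 for independent lists, and genes higher in DSS and lower with polydatin 29, against 36.3. The shared library pushes the comparisons in opposite directions, so part of the overlap of genes that moved in opposite directions may come from it. The simulated values leave out effects, and the independent ones leave out the shared library.

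**Figure D3:**
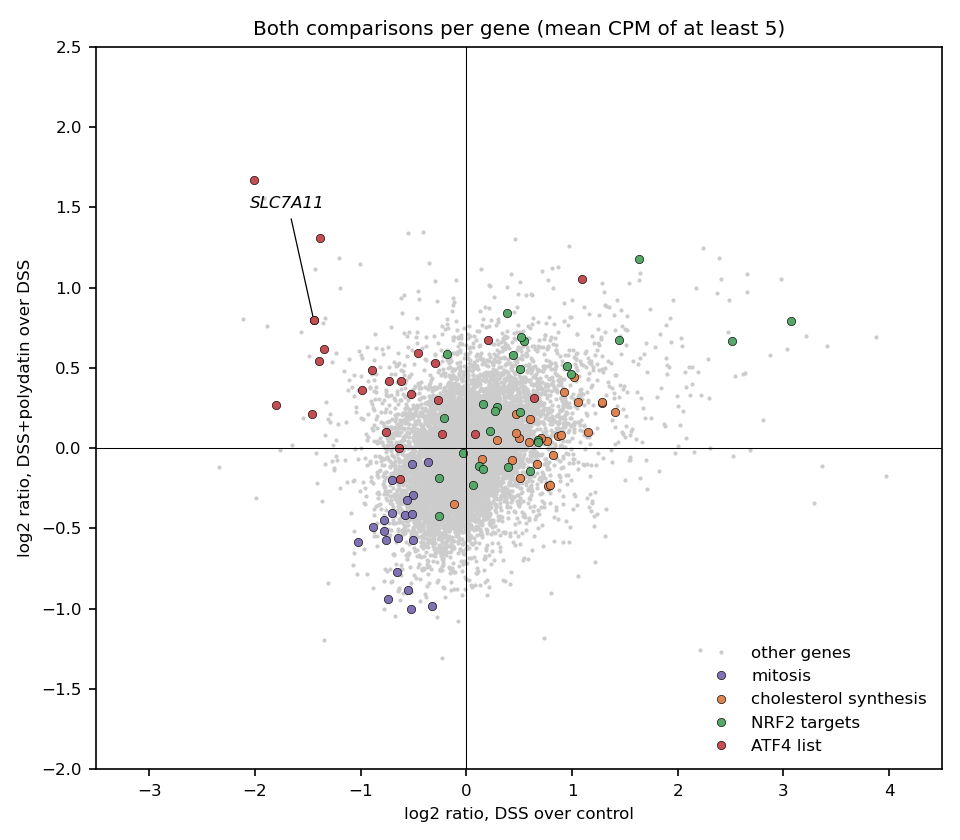
Log2 ratio of DSS over control (horizontal axis) against log2 ratio of DSS with polydatin over DSS (vertical axis), 1 point per gene for 11034 genes with a mean CPM of at least 5, of which 4 lie outside the axes. Most ATF4 list genes lie at the upper left, mitosis genes at the lower left, and NRF2 targets such as AKR1C1 at the upper right.

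Markers of other cell types gave few counts. The fibroblast list (5 measured members), endothelial list (3) and enteroendocrine list (2) were not apart in any comparison with the main settings. The fibroblast medians were −0.07, 0.19 and −0.32 for DSS against control, DSS with polydatin against DSS and DSS with polydatin against control, the endothelial medians 0.52, 0.43 and 0.95 (−0.75 and −1.36 for the latter comparisons with a CPM of at least 10, both apart), and the enteroendocrine medians 0.12, 0.71 and 0.83. The leukocyte list, with 3 members, was apart for DSS with polydatin against DSS (median −0.55, percentile 2.04), but not under 3 alternatives, and its median was 0.49 without the filter on low counts. Its medians were 0.42 for DSS against control and 1.17 for DSS with polydatin against control. It came to stand apart by its mean in the former (1.03, percentile 98.1) and without the filter in the latter (1.35, percentile 98.6). Without the filter the endothelial list was also apart, at 1.26 for DSS against control and −0.50 for DSS with polydatin against DSS. Counts of ALDOA were 13, 42 and 36 and of ASNS 61, 20 and 41 in control, DSS and DSS with polydatin, far below PGK1 at 9138, 12862 and 8426, and each of ALDOA and ASNS, named after their values were seen, overlaps 2 other genes in the annotation. Ratios followed GC content across 11017 genes, with Spearman rho of 0.35 for DSS against control, 0.23 for DSS with polydatin against DSS and 0.35 for DSS with polydatin against control.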

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

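The removal of the GC content and length trend, and thinning for single genes, were chosen after seeing the data. Of the alternative values computed, 80 counts and shares and 800 single-gene ratios kept their direction and their side of the threshold or stayed within their interval. For gene lists, 593 values kept their call. Some of those that were not apart turned sign, such as the mean of the aryl hydrocarbon receptor list for DSS against control. In addition 26 list values came to stand apart, among them values of the endothelial list that had turned sign. A further 26 ceased to stand apart, 2 of these turning sign, and 151 single-gene ratios moved outside their counting interval. Of 93 list medians, 63 kept their call under every alternative run on them. With a 1.5-fold rule the counts, by construction, were 1398 higher and 859 lower for DSS against control, 797 and 384 for DSS with polydatin against DSS, and 2367 and 1829 for DSS with polydatin against control. With a CPM of at least 10, which leaves fewer genes (10084 of 14792), they were 251 and 60, 30 and 9, and 509 and 232. The share closer to control was then 26.4%. No measured members of the leukocyte and enteroendocrine lists were left there. Without a filter, 121 genes were lower in DSS with polydatin than in DSS, and the share closer to control was 48.1%. The share was 41.8% with the GC content and length trend removed, which also gave log2 ratios of 0.14 (DSS against control) and −0.040 (DSS with polydatin against DSS) for KEAP1, −0.35 for GPX4 (DSS against control), and 0.088 for AGR2 in DSS with polydatin against control, where the main value was −0.14. Total-count scaling gave 0.20 for NFE2L2 and 0.25 for GPX4 in DSS with polydatin against DSS. Thinning left 3 lists apart and lower for DSS with polydatin against control. For DSS with polydatin against DSS, the leukocyte median turned to 0.49 without a filter and the enterocyte median to −0.051 with a CPM of at least 10. Except where construction or fewer genes is named, the cause was not tested. Depth limits low genes most, since a CPM of 1 is fewer than 20 counts. No paired analysis was possible because each group has 1 library.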

Other observations

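The tests of SLC6A12 with the GC content and length trend removed, the reading of the covariance against simulated libraries, and the tests of the NRF2 and ATF4 lists without SLC7A11 were chosen only after their results were seen. The 3 gene lists used below were written after the main results, with members whose values had been seen left out.

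Ribosome biogenesis genes were lower with polydatin. Their median log2 ratio was −0.21 for DSS against control (percentile 0.240 among matched random lists), with none of 24 members past 1.5-fold, and −0.61 for DSS with polydatin against DSS (percentile 0), with 13 lower and none higher. Against control, 20 of 24 were lower in DSS with polydatin. UTP20, a small-subunit processome gene, was at 0.543 times DSS (0.50 to 0.589, counting interval), the nucleolin gene NCL at 0.625 times (0.612 to 0.639), NOP56 at 0.629 times (0.601 to 0.659) and DKC1, dyskerin, at 0.592 times (0.557 to 0.629). These 4 examples were chosen after their values were seen.

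Genes for secreted proteins typical of liver, which Caco-2 cells also make, were lower in DSS by their median (log2 −0.31 over 13 members, percentile 0.60), with 5 lower and 2 higher. FGB was at 0.430 times control (0.392 to 0.472) and ITIH2 at 0.401 times (0.218 to 0.708), while SERPINA1, alpha-1-antitrypsin, was 3.25-fold (3.10 to 3.40) and VTN, vitronectin, 2.14-fold (2.01 to 2.28) higher, so the members moved both ways. With polydatin against DSS none passed 1.5-fold (median 0.11, percentile 87.2). FGB, ITIH2, SERPINA1 and VTN were named after their values were seen. Separately, CYP1A1, a member of the aryl hydrocarbon receptor list named above by rule, had 366 counts in control, 1733 in DSS and 683 in DSS with polydatin.

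SLC6A12, which overlaps 2 other annotated genes, led the DSS comparison at 66.4-fold. A GC content and length trend between the libraries is argued against by its size, since it shifted most genes by −0.14 to 0.28 log2. The SLC6A12 log2 ratio was 5.94 once that trend was removed. So small a trend could not have lowered this ratio much, so the removal adds no further support. A hyperosmotic response to the added DSS is a candidate explanation, since SLC6A12 encodes a betaine transporter and other osmolyte and NFAT5 target genes were higher as a list, with a median log2 ratio of 0.71 over 7 measured members, SLC6A12 left out (percentile 99.98), 4 of them past 1.5-fold higher, 3 within 1.5-fold and 1 of these below 0. Among them, named after their values were seen, SLC5A3, the myo-inositol transporter gene, was 4.91-fold higher (4.76 to 5.07) and AKR1B1, aldose reductase, 1.72-fold (1.53 to 1.93). Osmolality was not measured here, and reads of the overlapping genes and, with 1 library per group, a difference between cultures stay open.

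DSS with polydatin lay farther from control than DSS did for most genes at least 2-fold higher with DSS (25.2% of 627 lay closer), but not for those lower with DSS (69.7% of 261 lay closer), and without the filter on low counts 48.1% of all lay closer. Chance from the shared DSS library works the other way by design, toward a covariance below 0, and the observed covariance over all genes was 0.0358. That covariance does not single out the genes higher with DSS. Simulated Poisson libraries with no difference placed 91.0% of genes closer to control, a share not split by direction. For the genes higher with DSS, the 25.2% argues against that chance. For the genes lower with DSS, lying closer to control is what it would give. Their 69.7% fell short of the simulated share, so chance stays open there as a part. A GC content and length trend is argued against as the whole cause, since the covariance was 0.0250 once the trend was removed, although it was smaller. Reads from DNA or unspliced RNA that raise low genes are argued against as the whole cause, since the covariance was 0.0385 among genes with a mean CPM of at least 20, but a part stays open, since the lincRNA share of counts was 0.546% in control, 0.699% in DSS and 0.891% in DSS with polydatin and the protein-coding share 97.7%, 97.6% and 97.3%. An added effect of polydatin, and a difference in density or handling between single cultures, both stay open and may act together.

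SLC7A11 was lower in DSS and partly back with polydatin. Lower NRF2 activity in DSS is argued against by transcripts only, since the other NRF2 target genes had a median log2 ratio of 0.44 (percentile 100). Of these 29 genes, 24 lay above 0 and 5 below. HMOX1, named after its value was seen, was below, at 27.9 CPM in control and 24.1 in DSS with overlapping intervals. The whole list was already higher, and leaving out SLC7A11 could only hold or raise its median, so this adds no further support. NRF2 protein was not measured here. A GC content and length trend is argued against by its size, since it shifted most genes by −0.14 to 0.28 log2. The SLC7A11 log2 ratio was −1.41 once that trend was removed, a removal too small to add further support. Movement with ATF4 target genes, which include SLC7A11, is a candidate explanation, since the ATF4 list without SLC7A11 had medians of −0.68 for DSS against control and 0.39 for DSS with polydatin against DSS. Both medians use the same DSS library, so a deviation of that 1 culture would give these opposite signs, and a difference between cultures stays open, with ATF4 protein not measured here and the hypothesis found and tested on the same libraries.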
